A study of Mus musculus with 90 samples.

How the data were processed

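RNA from the left hippocampus and a piece of the left frontal cortex of APP/PS1 mice was measured on Illumina mouse bead arrays, 44 from hippocampus and 46 from frontal cortex. Per the labels, the animals belong to 4 groups per tissue, formed by the ASO (CD33 or control) and the infusion (14 or 28 days), and each array has an animal number. The arrays of 1 tissue and group come from separate animals, so p-values for the ASO and the duration measure the spread between animals. Up to 2 arrays, 1 per tissue, come from an animal.

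The authors' probe table gives for each array a signal intensity on a linear scale, from which background had been subtracted and which had not been normalized between arrays. The same table from the authors gives a detection p-value per probe and array, small where the probe lies above the negative controls. BeadStudio, GenomeStudio and Partek are named as tools per the submitters' processing notes, and their versions and settings are not given in the sources used here. A second table of the authors holds processed log2 values for 19542 of the 25697 probes. Within each array these had the same rank order as the signal, with 1 distribution over the hippocampal arrays (median 7.18) and another over the cortical arrays (median 7.29). The log2 base was read from the values, and the step that compressed low values there is not known. The 6155 probes left out of it had no detection p-value below 0.0501. This table was used as an alternative only. Median signal per array lay between 28.4 and 47.0.

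Probes were named through the platform annotation given with the arrays and checked against current gene records. Of the probes, 18348 had 1 gene symbol, 0 had several and 7349 were unnamed here. The named probes covered 13076 symbols, and 8 probes had a gene ID outside the reference table. Probe annotation can be old, and unnamed probes entered no gene test.

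Signals were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal and exponential model with the negative control level inferred from the detection p-values, adds an offset of 16, normalizes by quantiles over the 90 arrays and takes log2. The offset pulls fold changes of dim genes toward 0. Probes with a detection p-value under 0.01 in at least 9 arrays, the size of the smallest group, were kept, 13271 in all, and 1 probe per gene, that with the highest mean, gave 9741 genes. A probe counted as detected on an array at a detection p-value under 0.01. Where no array of a group detected a gene, its fold change is given as at least N-fold, or not at all where that falls under 1, from the mean of the brighter group over the mean, in the dimmer group, of the higher of the probe's own value and the lowest value of a detected probe on that array.

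Genes were tested with lmFit and eBayes of limma, 2-sided, with Benjamini-Hochberg adjustment over the 9741 genes and a threshold of 0.05, so that 487 genes would lie under an unadjusted p of 0.05 by chance. Adjusted p-values are from limma unless a permutation test is named. Each tissue had a model with 4 group means, and the contrasts were the CD33 ASO against the control ASO at each duration and averaged over both, 28 against 14 days within each ASO, and the difference of the ASO effects. Contrasts between tissues came from 1 model over 90 arrays with the animal as a random block (duplicateCorrelation, consensus correlation 0.128). Gene lists, 28 in number with 3 to 27 tested members each, were fixed before the data were examined, and 364 of their 460 members had a named probe. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 28 lists, with an estimated correlation as an alternative, and with fry, which asks whether a list moves on balance in 1 direction. Cd33 was also tested by permuting ASO labels, by exact enumeration at 14 days and with 100000 permutations at 28 days, and list means with 100000 permutations. Correlations of fold changes and the genes and directions shared by both tissues were set against 100 permutations of the labels among animals.

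The genes named were set by a rule fixed before the data were examined. For each CD33 ASO comparison these were Cd33 and the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, or the 10 of smallest p where fewer than 10 passed. For other contrasts they were the 5 up and 5 down, or the 5 of smallest p where fewer than 5 passed. From each list up to 4 passing members were taken, by size, or the 2 of smallest p. Genes that changed in both tissues are named in full, so that Apod, Srrm2, Dctn4 and Dnajc10 were chosen after their values were seen.

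The test was tried on simulated data with 200 changed genes among 9741. For the ASO comparison at 28 days it recovered 47.8%, 94.0% and 100% of log2 changes of 0.25, 0.5 and 1 in the hippocampus, with 11 false among 172 calls, and 50.7%, 88.1% and 100% in the frontal cortex, with 11 false among 170. At 14 days it recovered 46.3%, 80.6% and 98.5% in the hippocampus, with 13 false among 163 calls. In the frontal cortex it recovered 40.3%, 85.1% and 97.0%, with 15 false among 163. For 28 against 14 days with the control ASO 22 of 166 were false in the hippocampus and 17 of 168 in the frontal cortex. Between the regions 20 of 199 were false, and for the difference of ASO effects between tissues at 14 days 13 of 120. In most contrasts, the ASO comparisons at 14 and 28 days included, the share of false calls lay above the nominal one. The exceptions lay in the frontal cortex, both durations averaged (7 of 189) and 28 against 14 days with the CD33 ASO (7 of 160). The simulated noise was drawn separately for each gene and array, without chips, animals or correlated genes. With 200 changed genes the adjusted threshold is also easier to pass than where few genes change. The shares recovered may therefore overstate what the test finds in the data.

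Alternatives set before the data were examined were no background correction, median scaling, normalization within each tissue, the authors' processed values, no filter and a stricter filter on dim probes, all probes, the chip as a block, the replicate number as a block, no animal block, array weights, an intensity trend with robust fitting, only the groups compared, a threshold of 0.10, an estimated correlation for lists, and each array left out in turn. Chosen after seeing the data were the means of the choroid plexus, fibroblast and red blood cell lists as covariates, leaving out arrays rich in choroid plexus transcripts, and leaving Cd33 out of the lists that hold it. Figures were drawn with matplotlib.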

Results

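Gene expression was measured in the hippocampus and the frontal cortex of APP/PS1 mice, a double transgenic line that carries human genes of familial Alzheimer disease and deposits amyloid plaques. The mice received an antisense oligonucleotide (ASO, a short synthetic nucleic acid that lowers the transcript it pairs with) against Cd33, or a control ASO without a target, from an osmotic pump into the lateral ventricle. CD33 is an inhibitory sialic acid receptor of myeloid cells, and the series was set up to ask how lowering it affects microglial gene networks. Infusion of 40 µg per day, in 6 µL per day, started at 18 weeks of age and lasted 14 or 28 days, and all tissue was taken at 22 weeks. The pumps of the 14-day cohort were taken out at the end of the infusion, so these animals had a pump-free interval before collection, and the pumps of the 28-day cohort were replaced at the same point.

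The 90 arrays came from 47 animals, of which 43 had an array from both tissues. In the hippocampus there were 9 arrays per ASO at 14 days and 13 per ASO at 28 days. The frontal cortex had 9 per ASO at 14 days and 14 per ASO at 28 days. Between 42.8% and 51.6% of the probes of an array were detected, and the mean share per group lay between 47.6% and 49.9%. The number of arrays sets the precision of each value. Arrays of 1 group correlated at 0.976 to 0.994 over the probes, and 0 pairs were identical. The 12 chips each held 1 tissue and all 4 groups of it. The first principal component of the frontal cortex arrays held 17.4% of the variance and followed the chip (adjusted R2 = 0.877), while that of the hippocampus held 12.4% and followed it less (adjusted R2 = 0.110). The second hippocampal component, with 9.2% of the variance, followed the chip more (adjusted R2 = 0.537). Fold changes are given on the log2 scale with their standard error.

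The targeted gene was lower in every CD33 ASO group. In the hippocampus, Cd33 fell by 1.29 ± 0.17 at 14 days and fell by 1.46 ± 0.14 at 28 days (adjusted p = 2.8e-05 and 5.5e-09), to 41.0% and 36.4% of the control ASO level. Cortical Cd33 fell by 0.90 ± 0.13 at 28 days (adjusted p = 5.1e-05), to 53.7% of control. At 14 days the cortical difference was -0.69 ± 0.17, 61.8% of control, which did not pass over all genes (adjusted p = 0.33). For Cd33 on its own, 2-sided tests gave exact permutation p = 4.1e-05 in the hippocampus and 8.2e-05 in the frontal cortex at 14 days, and permutation p = 1e-05 and 3e-05 at 28 days. The first of these is the smallest an exact test of 9 against 9 arrays can give, and 1e-05 the smallest that 100000 permutations can give.

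The mean normalized intensity of Cd33 in the hippocampus at 28 days was 5.15 ± 0.56 (SD, n = 13) with the CD33 ASO and 6.60 ± 0.18 (SD, n = 13) with the control ASO. Frontal cortex levels at 28 days were 6.08 ± 0.52 (SD, n = 14) against 6.98 ± 0.27 (SD, n = 14). In the hippocampus 9 of 9 CD33 ASO arrays lay below the lowest control array at 14 days and 12 of 13 at 28 days, and in the frontal cortex 8 of 9 and 11 of 14. Of 21 animals labelled CD33 ASO with both tissues, 1 animal of the 28-day cohort had Cd33 within the control range in both, at 6.58 in the hippocampus (replicate 11) and 6.83 in the frontal cortex (replicate 12), and Avil, which was higher on most other CD33 ASO arrays, was undetected on both of its arrays. These arrays were kept as labelled. Without them Cd33 fell by 1.58 in the hippocampus and 0.96 in the frontal cortex at 28 days, and 42 and 59 genes passed in place of 40 and 46, without Mcm2 and Kcnj16 in the hippocampus. Cd33 was detected on 2 of 9 and 1 of 13 hippocampal CD33 ASO arrays and on all hippocampal control arrays, so the signal there was close to background and these fold changes understate the reduction. Except where the 28-day arrays alone are named, within-chip differences were taken over the arrays of both durations, as a chip holds few of each. Cd33 was lower within 6 of 6 chips in the hippocampus (-1.78 to -1.10) and within 6 of 6 in the frontal cortex (-1.33 to -0.14). With the chip as a block the 4 differences were -1.30, -1.46, -0.69 and -0.90.

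**Figure D1:**
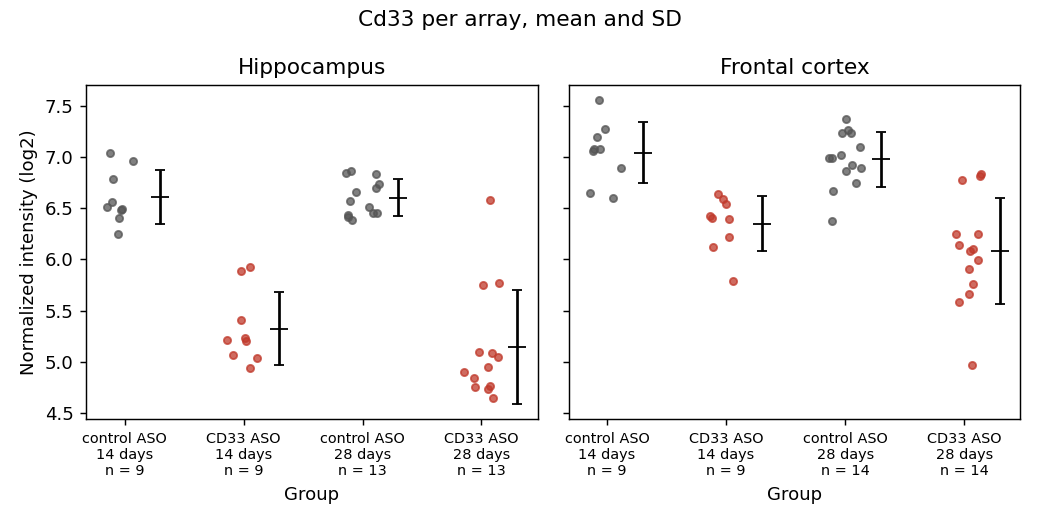
Normalized log2 intensity of Cd33 on each array (points) by group, with the mean and SD of each group in black. In the hippocampus at 14 days the 9 CD33 ASO arrays all lie below the 9 control ASO arrays, and in the frontal cortex at 28 days 11 of 14 lie below the lowest control array.

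Hippocampal genes that fell at 28 days included Ms4a7, Cbr2, Mrc1, Gpnmb, Lgals3 and Lyz2. Among 40 genes that changed, 16 rose and 24 fell, while median scaling of the arrays gave 32 higher and 21 lower. Those of the border macrophage list were Ms4a7, a marker of perivascular and meningeal macrophages (-1.08 ± 0.21), Cbr2, a carbonyl reductase of the same cells (-0.79 ± 0.14), and Mrc1, the mannose receptor CD206 (-0.73 ± 0.13). Those of the plaque-associated list were Gpnmb, a glycoprotein of lipid-laden phagocytes (-1.14 ± 0.18), Lgals3, which encodes galectin-3 (-1.15 ± 0.24), and Lyz2, lysozyme (-0.87 ± 0.17), each with n = 13 arrays per ASO. Avil, which encodes advillin, an actin-binding protein best known from sensory neurons, rose at least 1.94-fold (adjusted p = 1.7e-06).

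Fcna, the lectin-pathway recognition protein ficolin A, fell by 1.27 ± 0.19 (adjusted p = 1.1e-04) and was detected on 3 of 13 CD33 ASO and 13 of 13 control arrays. Vwf, von Willebrand factor of endothelial cells (-0.92 ± 0.17, adjusted p = 0.0021), and Anpep, aminopeptidase N (-0.72 ± 0.16, adjusted p = 0.015), fell too. Other rises were those of Sh3d21 (0.52 ± 0.11), Emc1 of the endoplasmic reticulum membrane complex (0.45 ± 0.08), the muscle ubiquitin ligase Fbxo32 (0.43 ± 0.09), the replication factor Mcm2 (0.40 ± 0.09), Acads, a mitochondrial acyl-CoA dehydrogenase (0.34 ± 0.07), the potassium channel Kcnj16 (0.32 ± 0.08), Fam53b (0.30 ± 0.07), the microtubule-associated Map7 (0.26 ± 0.06) and Czib (0.25 ± 0.05), with adjusted p from 0.0025 to 0.049. Second probes of Emc1 and Fam53b gave 0.03 and -0.03, so these 2 genes rest on a single probe. Avil was detected on 10 of 13 CD33 ASO and 0 of 13 control arrays, so that its rise has only a lower bound, with the control group set at the detection limit.

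Of 7 border macrophage and monocyte genes, 3 fell over all genes and 3 when adjusted over the list alone (camera, adjusted p = 1.6e-05, and adjusted p = 0.055 with an estimated correlation). Of 27 plaque-associated microglial genes, 3 fell, and 1 rose and 4 fell adjusted over the list alone. The remaining members went both ways, so that the list had a median of 0.01 but a mean of -0.09, and its shift did not pass (adjusted p = 0.17). In the list of microglial homeostasis, 8 of 16 genes lay below 0 (median -0.03), 0 changed in limma's test, and 1 fell adjusted over the list alone. Of 25 genes of the microglial TYROBP network, which centres on the adaptor of TREM2, 12 lay below 0 and 0 changed by either count (median 0.01, adjusted p = 0.73). Endothelial genes shifted down, with Vwf and Ly6c1 (-0.28 ± 0.06) fallen out of 9, and 3 adjusted over the list alone (adjusted p = 6.5e-05, and adjusted p = 0.055 with an estimated correlation). In antigen presentation 0 of 14 genes changed over all genes, and 4 fell adjusted over the list alone, among them H2-Aa (-0.79 ± 0.23, adjusted p = 0.14).

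Markers of tissue next to the hippocampus lay below 0 for most members in these CD33 ASO arrays. Choroid plexus and ependymal genes had a median of -0.63, with 9 of 10 below 0, such as transthyretin, Ttr (-0.99 ± 0.44), and 0 passing by either count (camera, adjusted p = 0.0027, and adjusted p = 0.51 with an estimated correlation). The 3 red blood cell genes had a median of -0.58, with 0 passing over all genes and 3 adjusted over the list alone (adjusted p = 2.3e-04, and adjusted p = 0.055 with an estimated correlation). Pericyte and fibroblast genes had a median of -0.20, 8 of 10 below 0 and 0 passing by either count (adjusted p = 0.0062, and adjusted p = 0.26 with an estimated correlation). With the means of these 3 lists as covariates, a fit chosen after the data were seen, 18 genes passed in place of 40. In that fit Ms4a7 fell short of the threshold at -0.64 ± 0.16 (adjusted p = 0.091) and Lgals3 at -0.91 ± 0.24 (adjusted p = 0.13), while Gpnmb, Lyz2, Cbr2 and Mrc1 passed, and the rises of Czib, Emc1, Fam53b, Fbxo32, Kcnj16, Map7 and Mcm2 no longer did. Kcnj16 also missed the threshold with the chip as a block. With the chip as a block 43 genes passed, and the border macrophage and endothelial lists shifted down with adjusted p = 2.0e-05 and 1.2e-04 at the preset correlation, although without the block both were lost with an estimated correlation (adjusted p = 0.055 each). Over both durations, the border macrophage list mean was lower within 6 of 6 chips (-0.51 to -0.13), the endothelial within 6 of 6 and the choroid plexus within 5 of 6 (-0.98 to 0.64). Each of Fcna, Gpnmb, Lgals3, Ms4a7, Cbr2, Mrc1, Lyz2 and Vwf was lower within 6 of 6 chips.

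**Figure D2:**
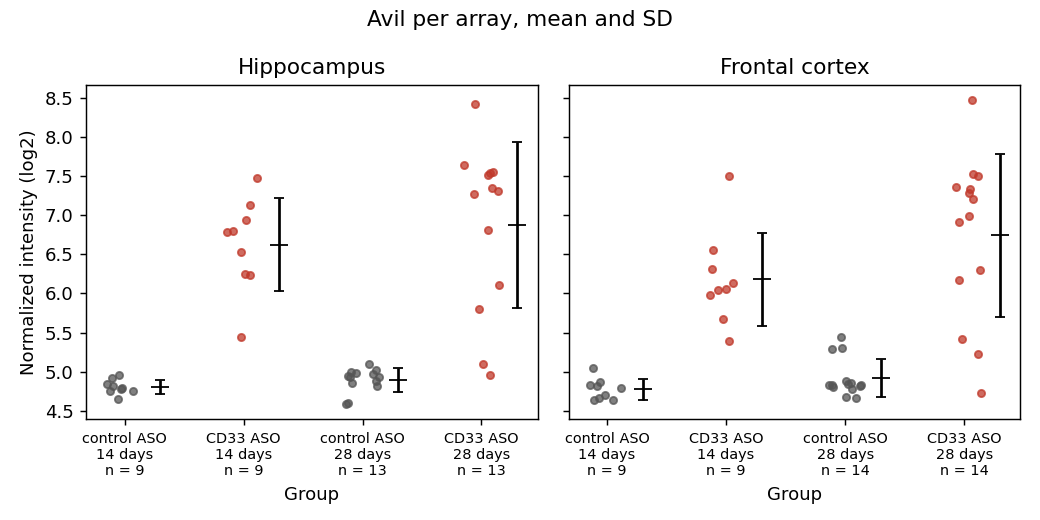
Normalized log2 intensity of Avil on each array (points) by group, with the mean and SD of each group in black. Control ASO arrays lie at the detection floor in both tissues, and the CD33 ASO arrays at 28 days spread widely, with an SD of 1.06 in the hippocampus (n = 13) and 1.04 in the frontal cortex (n = 14).

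The frontal cortex at 28 days showed a fall of 4 antigen presentation genes, together with Fcna, Gpnmb, Lgals3, Ms4a7 and Vwf. Of 46 genes that changed, 15 rose and 31 fell. The class II genes H2-Aa (-0.93 ± 0.20), H2-Eb1 (-0.87 ± 0.16) and H2-Ab1 (-0.83 ± 0.16) and their chaperone Cd74, the invariant chain (-0.75 ± 0.15), fell with n = 14 arrays per ASO. They passed in this tissue only, but other probes in the hippocampus at 28 days gave -0.78, -0.70 and -0.50 for H2-Ab1 and -0.79 for Cd74. All 4 genes were also lower within 6 of 6 hippocampal chips over both durations, so a difference between tissues was not shown. Fcna (-1.12 ± 0.14), Gpnmb (-1.09 ± 0.16), Lgals3 (-0.97 ± 0.22), Ms4a7 (-0.82 ± 0.14) and Vwf (-0.65 ± 0.09) fell as they did in the hippocampus. Avil rose again, at least 1.91-fold (adjusted p = 4.7e-06), as did Fpr2, a formyl peptide receptor of phagocytes (0.77 ± 0.13, adjusted p = 4.7e-04).

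Avil was detected on 11 of 14 CD33 ASO and 0 of 14 control arrays. Fpr2 was detected on 8 of 14 against 1 of 14 arrays, and without background correction neither it nor Gdpd3 passed. Smaller rises were seen for Sh3d21 (0.56 ± 0.10), Gdpd3 (0.49 ± 0.12), Emc1 (0.48 ± 0.08, with a second probe at 0.06), the phospholipase Gpld1 (0.42 ± 0.08), the microfibril protein Mfap2 (0.33 ± 0.06), Czib (0.33 ± 0.05), the kinase Nek3 (0.31 ± 0.05) and the Wnt pathway factor Tcf7l1 (0.27 ± 0.06). Other probes of Mfap2 gave 0.14 and 0.15, of Nek3 0.18 and 0.15 and of Gpld1 0.24, smaller than the values above. The alternative probes of Gpnmb, Lyz2, H2-Ab1 and Cd74 were lower too, at -0.60, -0.57, -0.53 to -0.79 and -0.75.

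In the antigen presentation list 4 of 14 genes fell, and 4 adjusted over the list alone, with 12 below 0. Its shift held with an estimated correlation (camera, adjusted p = 1.3e-07, and adjusted p = 0.031 with an estimated correlation). Endothelial genes did so as well, with Vwf fallen out of 9 and 3 adjusted over the list alone (adjusted p = 3.0e-05, and adjusted p = 0.031 with an estimated correlation). The list of Siglec and ITIM receptors, to which Cd33 itself belongs, had 7 of 8 genes below 0, with Cd33 alone passing over all genes and 2 adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.031 with an estimated correlation). Without Cd33, a test chosen after the data were seen, that shift did not pass (adjusted p = 0.068, and adjusted p = 0.32 with an estimated correlation). Of 16 Alzheimer risk genes, Cd33 and Ms4a6d (-0.40 ± 0.09) fell, and 2 adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.071 with an estimated correlation), or adjusted p = 0.036 without Cd33 and adjusted p = 0.32 with an estimated correlation. In the border macrophage list Ms4a7 fell out of 7, and 1 adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.060 with an estimated correlation). Of 27 plaque-associated genes Gpnmb, Lgals3 and Lyz2 (-0.50 ± 0.10) fell, and 4 adjusted over the list alone (adjusted p = 0.0038, and adjusted p = 0.34 with an estimated correlation). Among 25 TYROBP network genes 23 lay below 0 with a median of -0.07, 0 changed and 1 fell adjusted over the list alone (adjusted p = 0.0016, and adjusted p = 0.34 with an estimated correlation). Of 16 homeostatic microglial genes 12 lay below 0, 0 changed, and 1 rose and 2 fell adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.36 with an estimated correlation).

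Red blood cell genes had a median of -0.44 here, with 3 of 3 below 0 and 0 passing by either count (adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation), and choroid plexus genes one of -0.07, which did not pass (adjusted p = 0.27). Of the 10 pericyte and fibroblast genes Lum, a collagen-binding proteoglycan, fell (-0.53 ± 0.12), and 2 adjusted over the list alone (adjusted p = 0.086 for the list). With the 3 lists as covariates 43 genes passed and Lgals3 fell short of the threshold (-0.79 ± 0.22, adjusted p = 0.12). Each cortical chip held equal numbers of both ASOs at each duration, so the chip as a block left the fold changes as they were, and 65 genes passed with it. The antigen presentation list then shifted down with adjusted p = 8.2e-08, and its mean over both durations was lower within 6 of 6 chips (-0.42 to -0.10). H2-Aa, H2-Eb1, H2-Ab1, Cd74, Gpnmb, Fcna, Lgals3, Ms4a7 and Vwf were also lower within 6 of 6 chips, over both durations.

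**Figure D3:**
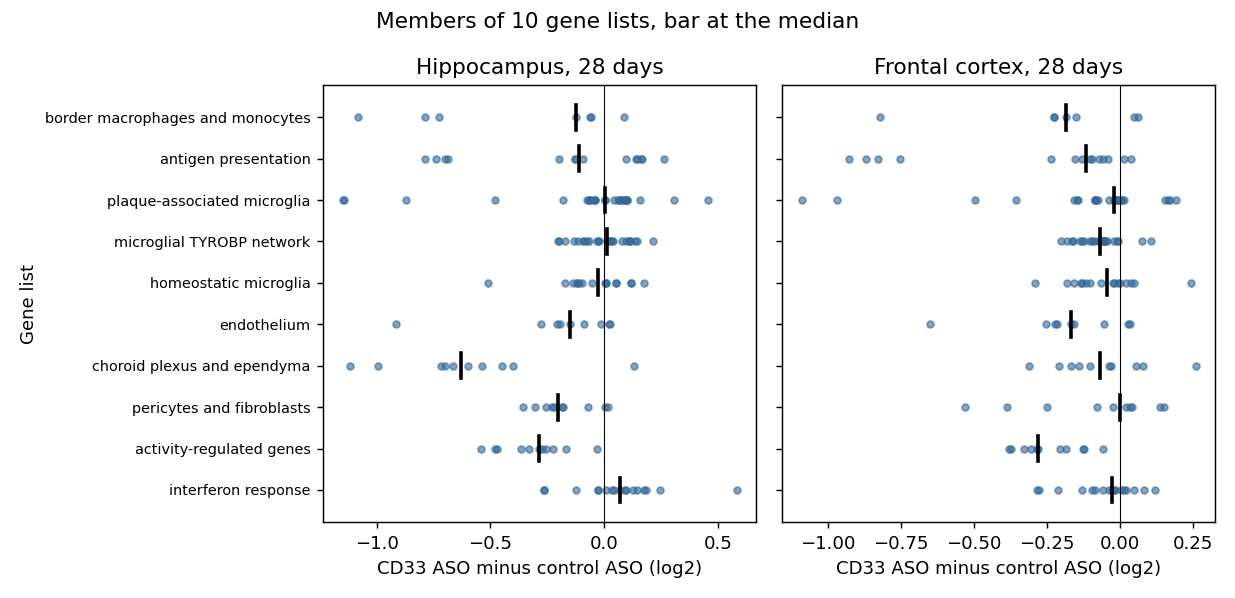
Log2 fold changes (CD33 ASO minus control ASO) at 28 days of the tested members of 10 gene lists (points), with the median of each list as a black bar, in the hippocampus (left) and the frontal cortex (right). The 4 antigen presentation genes that fell in the frontal cortex and the 3 border macrophage genes that fell in the hippocampus stand apart from the other members of their lists.

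Some of the same genes changed in both tissues at 28 days. Avil, Czib, Dctn4, Emc1 and Sh3d21 rose in both, 5 genes where 0.0246 would be shared by independent lists of these lengths. Apod, Cd33, Dnajc10, Fcna, Fyco1, Gpnmb, Lgals3, Lyz1, Lyz2, Ms4a7, Srrm2 and Vwf fell in both, 12 genes where 0.0764 would be. The fall of Lyz1 rests on a single probe, as its other probes were detected on 0 and 1 arrays. Because most animals gave both tissues, the ASO was also permuted 100 times among animals, in a test chosen after the overlap was seen, and lists of the same lengths were taken by limma's statistic. The permuted lists shared a median of 0 and at most 3 genes in each direction (permutation p = 0.0099 for both, the smallest that 100 permutations can give). Of the 40 genes that changed in the hippocampus, 40 lay in the same direction in the frontal cortex, 29 of them with an unadjusted p under 0.05. Of the 46 that changed in the frontal cortex, 44 did so in the hippocampus, 36 with an unadjusted p under 0.05. Of as many genes of smallest p under permuted labels, in a test also chosen later, a median of 26.5 and at most 38 of 40 lay in the same direction, and a median of 30 and at most 43 of 46. With an unadjusted p under 0.05 as well, the medians were 2 and 2.5 and the highest 10 and 14 (permutation p = 0.0099 for all 4).

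Across the 9741 genes, which are not independent replicates, the fold changes of the tissues correlated with r = 0.419 at 28 days (Spearman 0.273) and r = 0.236 at 14 days (Spearman 0.174). Both tissues came from the same animals, which raises this value without any ASO effect. When the ASO labels were permuted 100 times among animals, the median r was 0.165 at 28 days (permutation p = 0.020) and 0.106 at 14 days (permutation p = 0.059). The covariance was 0.00548 at 28 days against a permuted median of 0.00136, and 0.00317 at 14 days against 0.00127. Without Cd33 and Avil, r was 0.397 and 0.215. The CD33 ASO effect was not shown to differ between tissues for any gene over all genes, with 0 genes in limma at 14 days (458 at an unadjusted p under 0.05) and 0 at 28 days (496). For Cd33 tested on its own a difference was found, as given below. In simulated data this test recovered 49.3% of differences of 0.5 at 14 days and 71.6% at 28 days, so real differences may go undetected. The genes of smallest p were Atf4 at 14 days (-0.37 ± 0.10, adjusted p = 0.99) and Acvrl1 at 28 days (0.64 ± 0.15, adjusted p = 0.47), given as hippocampus minus frontal cortex, but hippocampal Acvrl1 was undetected in both groups at 28 days.

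**Figure D4:**
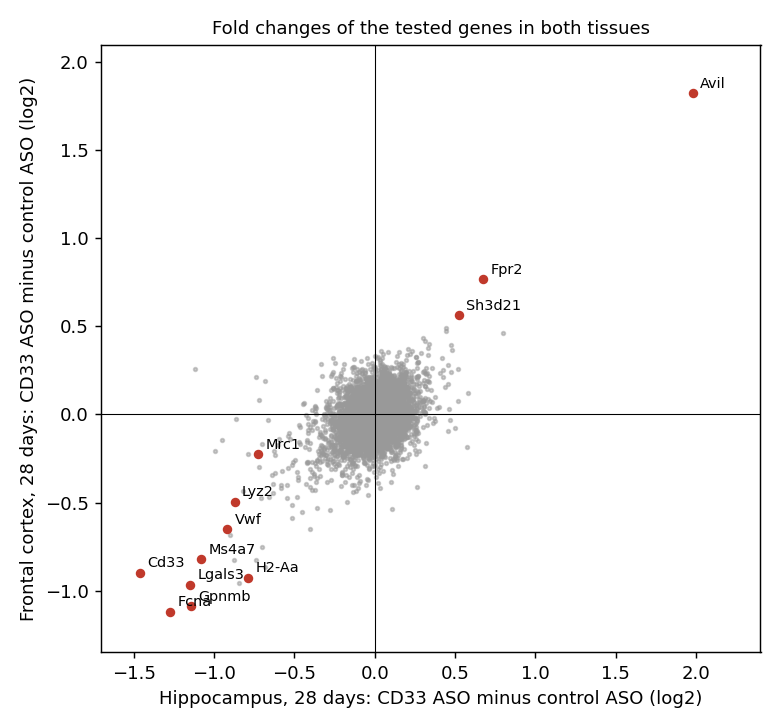
Log2 fold change of each tested gene at 28 days in the hippocampus (horizontal) and the frontal cortex (vertical), with named genes in red. Avil, undetected on control arrays, lies above 0 on both axes, and Cd33, Fcna, Gpnmb, Lgals3, Ms4a7, Vwf and Lyz2 lie below 0 on both axes.

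At 14 days, after the pump-free interval, few genes passed. In the hippocampus Avil rose at least 1.55-fold (adjusted p = 0.0010) and Cd33 fell, and these were the 2 genes that changed (577 at an unadjusted p under 0.05). In the frontal cortex 0 genes changed in limma (492 at an unadjusted p under 0.05), with Avil at least 1.29-fold higher (adjusted p = 0.21), Cd33 at -0.69 ± 0.17 and Gpnmb at -0.81 ± 0.20 (adjusted p = 0.33). Avil was detected on 8 of 9 hippocampal and 7 of 9 cortical CD33 ASO arrays and on 0 of 9 control arrays in each.

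The next genes by p in the hippocampus did not pass. They included Fbxo32 (0.49 ± 0.11) and the inflammatory caspase Casp4, detected on 4 of 9 CD33 ASO and 0 of 9 control arrays, both with adjusted p = 0.12, Pnpla7 (0.36 ± 0.09) and the collagen chaperone Serpinh1 (-0.55 ± 0.14), with adjusted p = 0.27 and 0.29. Those of the frontal cortex included Rspo3, a Wnt pathway ligand (0.43 ± 0.11), Camk1g (-0.41 ± 0.11) and Fyco1 (-0.46 ± 0.12), each with adjusted p = 0.49. Second probes gave 0.05 for Fbxo32 in the hippocampus and -0.02 for Camk1g in the frontal cortex. Interferon response genes lay above 0 in the hippocampus for 16 of 17 members, with a median of 0.31, 0 passing over all genes and 1 rising adjusted over the list alone, Ddx58, undetected on control arrays (camera adjusted p = 2.7e-04 for the list). That shift was lost with an estimated correlation (adjusted p = 0.73). With the chip as a block it had adjusted p = 1.9e-04, and the list mean over both durations was above 0 within 5 of 6 chips. Of the 25 TYROBP network genes, 24 lay below 0 in the frontal cortex with a median of -0.12 and 0 passing by either count (adjusted p = 4.3e-05, and adjusted p = 0.40 with an estimated correlation). Of 27 plaque-associated genes 20 lay below 0 there, 0 passed, and Gpnmb and Lgals3 (-0.88 ± 0.27) fell adjusted over the list alone (adjusted p = 0.0046, and adjusted p = 0.40 with an estimated correlation). Homeostatic microglial genes lay below 0 for 12 of 16, with 0 passing by either count (adjusted p = 0.040, and adjusted p = 0.44 with an estimated correlation).

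With both durations averaged, Gpnmb, Ms4a7, Fcna, Lgals3 and Vwf fell in both tissues. The hippocampus had 66 changed genes (37 rose, 29 fell, against 54 higher and 26 lower with median scaling) and the frontal cortex 62 (23 rose, 39 fell). In the hippocampus and the frontal cortex, respectively, the values were -0.98 ± 0.14 and -0.95 ± 0.13 for Gpnmb, -0.99 ± 0.16 and -0.67 ± 0.11 for Ms4a7, -0.91 ± 0.15 and -0.87 ± 0.12 for Fcna, -0.87 ± 0.18 and -0.92 ± 0.17 for Lgals3 and -0.68 ± 0.13 and -0.52 ± 0.07 for Vwf. Avil rose at least 1.73-fold and 1.57-fold (adjusted p = 5.4e-09 and 6.0e-07). In the hippocampus Lyz2, Cbr2, Anpep and Lyz1 fell (-0.56, -0.51, -0.57 and -0.51), and in the frontal cortex H2-Ab1, Fyco1, the apolipoprotein Apoc1 and the histone gene H4c8 (-0.53, -0.48, -0.47 and -0.46). The value of Lyz1 rests on a single probe here too.

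Rises in the hippocampus included Sh3d21 (0.47 ± 0.08), Fbxo32 (0.46 ± 0.07), the checkpoint receptor gene Lag3 (0.42 ± 0.09), Xntrpc (0.41 ± 0.08), the apolipoprotein Apoa1 (detected on 7 of 22 CD33 ASO and 0 of 22 control arrays), Hsf5 (0.37 ± 0.08), Aspdh (0.33 ± 0.07), Bicc1 (0.31 ± 0.08) and Rac3 (0.31 ± 0.08). Rises in the frontal cortex included Aox3 (0.45 ± 0.11), Aspdh (0.44 ± 0.09), Gdpd3 (0.43 ± 0.10), Sh3d21 (0.39 ± 0.08), Gpld1 (0.36 ± 0.06), Rspo3 (0.32 ± 0.07), Mfap2 (0.31 ± 0.05), Emc1 (0.30 ± 0.07) and Flrt2 (0.25 ± 0.05). The stress response factor Atf4 fell in the hippocampus (-0.25 ± 0.05, adjusted p = 0.0034), the only 1 of 13 DNA damage and stress genes to pass. Myelin genes shifted down in the hippocampus, where Mog (-0.41 ± 0.10) and Cldn11 (-0.19 ± 0.04) fell out of 12, and 5 adjusted over the list alone (camera, adjusted p = 2.5e-05, and adjusted p = 0.27 with an estimated correlation). Among cortical microglial and astrocyte genes, Laptm5, a lysosomal membrane protein of the TYROBP network (-0.16 ± 0.04), Ltc4s of the homeostatic microglial list (-0.27 ± 0.06) and the astrocyte gene Atp1b2 (-0.14 ± 0.04) fell. With the chip as a block 74 and 90 genes passed, without Apoa1 and Rac3 in the hippocampus. Second probes in the hippocampus gave -0.03 for Aspdh, 0.06 for Rac3 and 0.20 for Fbxo32, so the rises of Aspdh and Rac3 there rest on a single probe. Those in the frontal cortex gave 0.26 for Aspdh, 0.20 for Gpld1, 0.12 and 0.14 for Mfap2, 0.03 for Emc1 and -0.15 for Apoc1.

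Infusion for 28 days was set against 14 days within each ASO, which asks how the tissue at the end of infusion differs from that after the pump-free interval at the same age. With the control ASO, the cohesin subunit Stag2 rose by 0.30 ± 0.05 and Fam53b fell by 0.46 ± 0.08 in the hippocampus, 2 genes in all (1060 at an unadjusted p under 0.05). A second probe of Fam53b gave -0.32, but that of Stag2 gave -0.13, so Stag2 rests on a single probe. With the CD33 ASO, 3 hippocampal genes fell, the oligodendrocyte phosphodiesterase Enpp6 (-0.67 ± 0.13), the Rac regulator Chn2 (-0.39 ± 0.08) and Tril, an accessory protein of Toll-like receptors (-0.29 ± 0.06), with 935 genes at an unadjusted p under 0.05. These 3 calls ended with the chip as a block, where 0 genes passed. In the frontal cortex 0 genes changed in limma with the control ASO (445 at an unadjusted p under 0.05) and 0 with the CD33 ASO (505), where Fpr2 had the smallest p (at least 1.20-fold higher, adjusted p = 0.20).

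The CD33 ASO effect itself was not shown to differ between 28 and 14 days for any gene, with 0 genes in limma in the hippocampus (459 at an unadjusted p under 0.05) and 0 in the frontal cortex (261). The smallest p values belonged to Fam53b in the hippocampus (0.52 ± 0.11, adjusted p = 0.16) and to Xpo6, Capza1 and Fpr2 in the frontal cortex (each with adjusted p = 1.00), Fpr2 being undetected in both groups at 14 days. In data simulated at this size, the same test recovered 93.9% of differences of 1 in either tissue but 17.9% of those of 0.25, so smaller changes with duration stay undetected. The simulated noise was independent between genes and arrays, so these shares may overstate recovery. Across genes the fold changes at 14 and 28 days correlated with r = 0.204 in the hippocampus (Spearman 0.131) and r = 0.363 in the frontal cortex (Spearman 0.317). These cohorts share no animals, and permuted labels gave median r of 0.0150 and 0.0024 (permutation p = 0.050 and 0.020).

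The comparison of both regions in control ASO animals checked the tissue labels. Most genes of striatal neurons and of neocortex were higher in the frontal cortex pieces, and most hippocampal and choroid plexus genes were higher in the hippocampus. Genes higher in the frontal cortex included Ido1 (at least 9.65-fold, as 0 of 22 hippocampal arrays detected it), the LIM homeobox gene Isl1 (detected on 23 of 23 cortical and 1 of 22 hippocampal arrays), Rasgef1c (3.81 ± 0.08, detected on 17 of 22 hippocampal arrays), the tachykinin gene Tac1 (3.61 ± 0.07) and the sodium channel subunit Scn4b (3.48 ± 0.08). Lower were Ttr (-6.96 ± 0.31), C1ql2 (-5.91 ± 0.09), Spink8 (-3.74 ± 0.08), Fibcd1 (-3.45 ± 0.06) and Cabp7 (detected on 2 of 23 cortical and 22 of 22 hippocampal arrays). Of 8 striatal genes 8 were higher in the frontal cortex with a median of 2.41, of 12 neocortical genes 9 were higher and 3 lower (median 0.68), and of 9 hippocampal genes 5 were lower and 2 higher (median -0.33). The striatal genes differed more than the neocortical ones, so the pieces labelled frontal cortex probably held striatal tissue too. Its share was not among the covariates of the ASO comparisons.

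In all, 6362 genes differed between the regions, 2988 higher and 3374 lower in the frontal cortex (6607 at an unadjusted p under 0.05). The authors' processed values, which had a distribution of their own in each tissue, gave 4090 higher and 2113 lower. Of 25 TYROBP network genes 25 were higher in the frontal cortex (median 0.59), as were 12 of 16 homeostatic (median 0.43) and 19 of 27 plaque-associated microglial genes (median 0.46). Activity-regulated genes were higher for 8 of 11 (median 0.83) and antigen presentation genes for 10 of 14 (median 0.40). Choroid plexus genes were lower for 9 of 10 (median -2.13). Each chip held a single tissue, so a difference between chips adds to these values.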

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

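The tests of a difference between chips for each pattern, of fewer microglia of all kinds, and of chance assignment of animals were chosen after the results were seen, the chip block for the activity-regulated list after a count over chips had left it undecided, as were the fits with 3 list means as covariates and the relations without 1 animal.

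Among arrays of the frontal cortex at 14 days, the highest of 9 CD33 ASO arrays for Gpnmb lay far from the others, at 10.38 against 9.56 for the next and 8.95 for the lowest, a gap of 0.571 of the range. The highest of 9 control ASO arrays for Lin37 lay at 6.48 against 6.22 for the next and 5.98 for the lowest, a gap of 0.505. In 40 groups of values tested this way 2 were picked out, and 2 would be by chance.

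The CD33 ASO effect on Cd33 was larger in the hippocampus than in the frontal cortex, by -0.59 ± 0.22 at 14 days (limma, adjusted p = 0.020 over the 4 differences tested for Cd33, and 0.99 over all genes) and by -0.57 ± 0.18 at 28 days (adjusted p = 0.011 over the 4, and 0.76 over all genes). Because hippocampal Cd33 lay near background with the CD33 ASO, these differences are understated.

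Of the 810 unnamed probes that passed the detection filter, 2 were higher with the CD33 ASO in the hippocampus at 28 days and 3 with both durations averaged. Of the same probes, in the frontal cortex 4 were higher and 1 lower at 28 days, and 3 were higher and 4 lower with both durations averaged. Their genes are not named here.

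For Avil, higher with the CD33 ASO in both tissues, a difference between chips is argued against by its being higher within 12 of 12 chips, and more choroid plexus, fibroblasts or blood in the CD33 ASO pieces by the share of the fold change kept with the 3 list means as covariates, which was at least 1.01. Among CD33 ASO animals Avil was higher where Cd33 was lower, with r = -0.833 in the hippocampus (n = 22, Spearman -0.790, permutation p = 1e-05 and 9e-05, adjusted p = 2.3e-05 over 7 relations, r = -0.773 without the 2 farthest arrays) and r = -0.718 in the frontal cortex (n = 23, Spearman -0.692, permutation p = 4.3e-04 and 4.5e-04, adjusted p = 7.5e-04, r = -0.532 without 2). Avil also correlated between the tissues of an animal at r = 0.927 (n = 21, Spearman 0.935, permutation p = 1e-05, the smallest these permutations can give, r = 0.876 without 2), and on control ASO arrays it was at background, so that these relations have no control to set against. Without the animal whose Cd33 was within the control range in both tissues the 3 values were r = -0.780, -0.655 and 0.903. Most hippocampal CD33 ASO arrays did not detect Cd33, so its relation with Avil there rests largely on values near background. A candidate explanation is a signal that follows the exposure of the animal to the CD33 ASO, as a hypothesis found on the same data, and whether it comes from lower CD33 or from the oligonucleotide itself stays open, since 1 CD33 ASO was compared.

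At 28 days some macrophage and plaque-associated genes in both tissues, and 4 antigen presentation genes in the frontal cortex, were lower with the CD33 ASO. For 28 minus 14 days other probes of H2-Ab1 gave 0.31 to 0.63 in the hippocampus and 0.39 to 0.48 in the frontal cortex with the control ASO. With the CD33 ASO they gave -0.07 to -0.03 and -0.18 to -0.05. A second probe of Cd74 gave 0.43 and 0.31 with the control ASO, and -0.25 and -0.27 with the CD33 ASO. These values carry no test, and no gene of this pattern passed for 28 against 14 days or for the difference of the ASO effects. Without a group given no ASO, which of the 2 groups moved, if any, cannot be told. Over the 28-day arrays alone, of which a chip holds few, the mean of the passing genes was below 0 within 12 of 12 chips. However, these genes were picked for their fall on the same arrays. Means of the whole lists, over both durations, argue against a difference between chips. They were lower within 6 of 6 hippocampal and 5 of 6 cortical chips (border macrophages), 5 and 6 (plaque-associated), and 6 and 6 (antigen presentation). The homeostatic microglial median was -0.03 ± 0.050 in the hippocampus and -0.04 ± 0.038 in the frontal cortex. These errors were taken over 16 genes of the same animals, so they do not measure the spread between animals. Both medians were at most 0.0513 of the median of the passing genes, -0.98 and -0.85, a ratio made smaller by picking those genes for their fall. The medians argue against a loss of all microglia as large as these falls, and a smaller loss stays open. Less choroid plexus, fibroblast or blood tissue in the CD33 ASO pieces cannot be told apart from an effect on the cells, because the covariates kept a median share of 0.849 ± 0.074 in the hippocampus and 0.805 ± 0.019 in the frontal cortex, while 4 of 6 and 7 of 8 genes stayed past the threshold. The errors of these shares were likewise taken over genes and not over animals. The calls that ended were Lgals3 in both tissues, from -1.15 to -0.91 ± 0.24 and from -0.97 to -0.79 ± 0.22, and Ms4a7 in the hippocampus, from -1.08 to -0.64 ± 0.16, each through a smaller fold change. A change in microglia and border macrophages may account for the rest, but neither their uptake of the ASO nor their number was measured. Whether it would come from lower CD33 or from the oligonucleotide itself stays open here too.

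Activity-regulated genes lay below 0 at 28 days for 11 of 11 members in each tissue, with 0 past the threshold by either count and a list shift (camera, adjusted p = 4.2e-04 and 6.2e-04) that was lost with an estimated correlation (adjusted p = 0.44 and 0.34). The list mean over both durations was below 0 within 10 of 12 chips, which left a difference between chips undecided. Chips as the whole cause are argued against by the hippocampal list mean difference with the chip as a block, -0.34 ± 0.16 against -0.33 ± 0.16 without it, a share of 1.03 ± 0.191 (jackknife), and in the frontal cortex by equal numbers of both ASOs on each chip, with which a chip's offset cancels. The list mean correlated between the tissues of an animal at r = 0.799 (n = 43, Spearman 0.738, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 2.3e-05, r = 0.692 without 2), which is what a state of the animal at death, shared by both tissues, would give. Permuting the ASO among animals gave adjusted p = 0.072 over the 28 lists, so a chance assignment of animals in such states could also have made the difference, and no explanation through CD33 was tested.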

How the results depend on the processing

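The fit with 3 list means as covariates and the lists without Cd33 were chosen after the data were seen. Across all settings that leave every array in, 168 of 191 counts stayed within 1.5 times their value, and of 1946 values of named genes 58 lost and 17 gained the threshold. Of 406 list shifts 72 lost it, and the 12 correlations of fold changes stayed within their error. No gene, list shift or correlation changed its sign in these settings. The setting with all probes took the probe of smallest p for each gene, so a second probe that disagreed could go unseen. Second probes in the hippocampus did have the other sign for Stag2 (-0.13, 28 against 14 days, control ASO), Fam53b (-0.03, ASO effect at 28 days) and Aspdh (-0.03, ASO effect over both durations). The gene calls lost under the most settings were those of Kcnj16, Rac3, Gdpd3, Enpp6, Tril and Chn2. The cause was not tested unless a setting's construction shows it.

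In the hippocampus at 14 days, in place of 2 genes, 1 passed with a stricter filter, 4 with only the groups compared and 4 with the covariates. At 28 days 62 passed with array weights and 18 with the covariates, in place of 40. In the frontal cortex at 14 days, in place of 0, 1 passed with no background correction and 1 with only the groups compared. A threshold of 0.10 gave 74 genes at 28 days and 112 over both durations by construction.

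For 28 against 14 days with the CD33 ASO in the hippocampus, in place of 3, 0 passed with median scaling, no filter, the chip as a block, all probes or only the groups compared, 1 with the replicate block and 26 with array weights. With the control ASO, in place of 2, 4 passed with the trend and robust fit, 6 with all probes, 8 at a threshold of 0.10 and 0 with only the groups compared. In the frontal cortex, in place of 0, the replicate block gave 11 with the control and 45 with the CD33 ASO, and array weights gave 1 with the CD33 ASO.

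With an estimated correlation, the homeostatic, TYROBP and plaque-associated lists lost their call in the frontal cortex at 14 days (adjusted p = 0.441, 0.396 and 0.396) and at 28 days (0.365, 0.343 and 0.343). The balance of higher to lower genes did turn. In the hippocampus at 28 days it went from 16 against 24 to 32 against 21 with median scaling, and between the regions from 2988 against 3374 to 4090 against 2113 with the authors' values. Over both durations in the hippocampus it went from 37 against 29 to 27 against 31 with the trend and robust fit, to 25 against 29 and 28 against 29 without control ASO replicate 2 or 12 at 28 days, and to 54 against 26 with median scaling. For 28 against 14 days there with the CD33 ASO it went from 0 against 3 to 15 against 11 with array weights and to 1 against 0 without replicate 2 at 28 days. Same-numbered arrays deviated together, at a correlation over 0.1, in 3 of 9 and 5 of 13 pairs in the hippocampus and 5 of 9 and 11 of 14 in the frontal cortex. In the frontal cortex 9 of 9 and 14 of 14 same-numbered pairs shared a chip. Their mean correlation was 0.180 at each duration, against 0.123 and 0.174 for other pairs on the same chip. The replicate number there goes with the chip, and in the hippocampus most pairs did not deviate together.

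Leaving out 1 array in turn gave 29 to 45 genes in the hippocampus at 28 days and 52 to 79 over both durations, and 36 to 59 and 47 to 73 in the frontal cortex. In the hippocampus the difference between durations ranged from 0 to 1 (1 without control ASO replicate 1 at 14 days). There 28 against 14 days gave 2 to 5 with the control ASO (4 without replicate 3 at 14 days, 5 without replicate 11 at 28 days) and 0 to 4 with the CD33 ASO (0 without replicate 1, 3, 5, 8 or 9 at 14 days or 4, 5, 7, 8, 9 or 13 at 28 days, 1 without replicate 2, 6 or 7 at 14 days or 2 at 28 days). In the frontal cortex it gave 0 to 1 with the CD33 ASO (1 without replicate 11 at 28 days). No array lay over 3 median absolute deviations above its tissue's median choroid plexus level, so none was left out for that. Signal near background limits the fold changes of Cd33 in the hippocampus and of Avil in both tissues.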

Other observations

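The tests of other splits of the arrays were set before the results were seen, while the permutation of list means among animals, the lists without Cd33 and the refits of splits with the chip as a block were chosen after.

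Beyond the lists already described, activity-regulated genes, the immediate early transcripts of neuronal firing, lay below 0 in every member at 28 days, 11 of 11 in the hippocampus (median -0.28, camera adjusted p = 4.2e-04, and adjusted p = 0.44 with an estimated correlation) and 11 of 11 in the frontal cortex (median -0.28, adjusted p = 6.2e-04, and adjusted p = 0.34 with an estimated correlation). In both, 0 members passed limma's test over all genes and 0 adjusted over the list alone, Fos being at -0.48 and Egr1 at -0.33 in the hippocampus. Striatal genes lay below 0 for 8 of 8 in the frontal cortex at 28 days (median -0.14, adjusted p = 0.0059, and adjusted p = 0.34 with an estimated correlation), with 0 passing by either count. Complement genes had 5 of 7 below 0 there (adjusted p = 0.0099, and adjusted p = 0.34 with an estimated correlation), with 0 passing over all genes and 2 fallen adjusted over the list alone.

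Myelin genes lay below 0 for 10 of 12 in the hippocampus at 14 days (median -0.09, adjusted p = 0.0010, and adjusted p = 0.69 with an estimated correlation) and for 9 of 12 at 28 days (median -0.05, adjusted p = 0.0017, and adjusted p = 0.43 with an estimated correlation), with 3 and 4 fallen adjusted over the list alone and 0 over all genes. When ASO labels were permuted among animals and the list mean taken over both tissues and durations, 5 of 28 lists were lower at an adjusted p under 0.05. These were Alzheimer risk genes (-0.12), Siglec and ITIM receptors (-0.19) and border macrophages (-0.23), each with permutation p = 1e-05, the smallest these permutations can give, and adjusted p = 9.3e-05, endothelium (-0.13, adjusted p = 2.1e-04) and myelin (-0.11, adjusted p = 0.024). The first 2 of these lists hold Cd33 itself, which makes up much of their value. Without it the Siglec and ITIM receptors stood at -0.06 (permutation p = 0.017, adjusted p = 0.072) and the Alzheimer risk genes at -0.05 (permutation p = 0.0019, adjusted p = 0.018), and 4 of 28 lists were lower.

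Regrouping the arrays at random, 100 splits with the real one included, asked whether chance can be excluded for each count. It can for the hippocampus at 28 days (40 genes, highest other 1, 1 split as large) and over both durations (66, highest other 2, 1 split), and for the frontal cortex at 28 days (46, highest other 1, 1 split) and over both durations (62, highest other 5, 1 split). It can also for the regions (6362, highest other 2023, 1 split). For the 2 genes of the hippocampus at 14 days (highest other 2, 2 splits) another split gave as many. That lies under the bound of 5 splits set beforehand, but so small a count does not exclude chance by itself. These shares of splits were not adjusted over the counts tested. For 28 against 14 days in the hippocampus with the control ASO (2 genes, highest other 24, 4 splits) chance stays open. The 4 splits lie under the bound of 5 set beforehand, but only just, and 0 genes passed with only the groups compared. For 28 against 14 days in the hippocampus with the CD33 ASO (3 genes, highest other 1, 1 split) random regrouping is excluded as well, yet 0 genes passed with the chip as a block, with median scaling or without any 1 of 11 arrays, so the splits do not make these calls firm. For the counts of 0 the splits decide nothing, since 100 of 100 gave at least as many. Their highest other splits gave 3 genes for the frontal cortex at 14 days, 1 and 3 for the difference between durations in the hippocampus and the frontal cortex, 2 and 154 for 28 against 14 days in the frontal cortex with the control and the CD33 ASO, and 3 and 2 for the difference between tissues at 14 and 28 days. The splits with 24 and 154 genes point to a structure among the samples other than the groups, and with the chip as a block both gave 0 genes, whereas the split with 2 genes for the control ASO in the frontal cortex then gave 7.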
